A study of Mus musculus with 15 samples.

How the data were processed

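Small RNA was sequenced from total RNA of 15 mouse tissues and embryo stages, with 1 library per tissue. Per the labels' protocols, the RNA came from a commercial panel, small RNAs were selected by size on a gel, and adapters with randomized ends were ligated to both ends, a procedure called AQ-seq that is meant to lower ligation bias. Ligation bias matters here because it could favour 1 arm of a hairpin over the other. The protocols also describe synthetic spike-in RNAs. The deposited counts list mouse miRNA names only, so no scaling to spike-ins was made.

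The deposited files hold read counts per mature miRNA name for each library. Per the submitters' processing notes, bcl2fastq version 1.8.4, cutadapt, BWA and bedtools were used with the mouse build mm10. The role of each tool, its options, the miRNA annotation release and the handling of reads that map to several loci are not given in the sources used here. Names without a read are not listed in a library, and they were taken as 0. Across the libraries 1558 mature names occurred, printed here without their species prefix. Of these, 130 had no arm ending, and 615 hairpins had both a 5p and a 3p name, which together held 70.2% of reads. Among names with at least 100 reads, 5 pairs had identical counts in all libraries, such as miR-467a-5p and miR-467b-5p. The counts of miR-199a-3p and miR-199b-3p differed by at most 0.53%. The values of such names are uncertain, since the counting may have shared reads between them.

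Tissue classes were set from the tissue names before the data were examined. Brain, spinal cord and eye formed the nervous class, the 11-, 15- and 17-day embryos the embryo class, and the 9 remaining tissues the other adult class. For the 17-day embryo the title and the source field of the labels disagree on the day, and the title was used. A chi-square test of the counts of the 15- and 17-day embryos gave 248 per degree of freedom over 651 miRNAs, so the files are not 1 library deposited under both names, but this does not bear on which day is right. Across miRNAs their log2 CPM values had a Pearson r of 0.990, the highest of all pairs of libraries. The labels do not say how many animals the RNA came from. With 1 library per tissue there is no replicate of any tissue. All p-values measure the spread between tissues or stages of a class, which may be in part technical, and not the spread between animals. Both class comparisons use the same 9 other adult libraries and were not compared with each other.

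The 5p share of a hairpin is its 5p reads as a percent of its 5p and 3p reads, with an exact Clopper-Pearson 95% interval. A hairpin was counted as switching arms when the 99% interval of this share lay wholly above 50% in at least 1 library and wholly below 50% in at least 1 other, among libraries with at least 20 reads of the hairpin. In 100 simulations with the share of each hairpin held constant and counting error only, the rule found at most 1 switch. It found 100 of 100 switches placed at shares of 30% and 70% in hairpins with at least 20 reads in at least 10 libraries. Smaller switches were not simulated. Spread beyond counting error was not simulated either, although 187 of 219 such hairpins had it, so the rate of false switches in these data is not known. Class means of a share take in all libraries with a read of the hairpin, including those with fewer than 20 reads. Intervals cover counting error only, since reads amplified by PCR are not independent molecules.

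Class differences in the mir-324 share were tested with a two-sided exact permutation test over the 220 splits of 12 libraries, whose smallest possible p is 0.0045. Arm usage of all hairpins was tested with the quasi-likelihood test of edgeR 4.0.16 in R, on 5p and 3p counts with a term per library and the interaction of arm and class. Hairpins needed at least 20 reads in at least 8 libraries. Abundance was tested with the same tool on counts per mature name, after TMM scaling and removal of low counts with filterByExpr. Both fits used all 15 libraries, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. CPM values are counts scaled by TMM and by the reads left after the filter, so that they can exceed the raw share of reads. The filter removed 13.1% of the reads of the testis library and at most 0.21% of those of any other.

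In counts simulated for the nervous comparison of abundance over 664 names, 31.9% of 4-fold and 78.8% of 16-fold changes were recovered, and 1.82% of calls were false. For the nervous comparison of arm usage over 226 hairpins these values were 60.0%, 100% and 8.57%. Changes of 4-fold in abundance can therefore be missed.

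The 19 miRNA lists were fixed before the data were examined and tested with fry, which asks whether the members of a list move on balance in 1 direction, and with camera and an estimated correlation, which compares the list with all other miRNAs. In single libraries a list is described by its median difference from the other 14 libraries in log2(CPM + 1), with its percentile among 10000 random lists matched on mean level. A miRNA was called tissue-enriched at 100 CPM or more, at least 8 times the median of the other libraries and at least 2 times the next library. Against a class with no read, folds are lower bounds computed with 3 counts over the whole class.

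The named items follow a rule fixed before the data were examined. They are mir-324, the 15 switching hairpins of widest range with the 3 hairpins of narrowest range, the 10 hairpins of lowest adjusted p per arm comparison, and the 10 largest rises and 10 largest falls per abundance comparison among miRNAs whose classes did not overlap and whose mean was at least 10 CPM in the higher class. Up to 3 enriched miRNAs per tissue, list members of highest mean CPM and the most abundant miRNA of each library complete the rule. mir-324 was chosen because it is the hairpin that the study is known for. Its p-values are therefore not those of a hairpin picked blind to these data. Alternatives covered interval levels, read minimums, other scalings, limma and DESeq2 as other tools, smaller sets of libraries and the removal of each library. Genomic positions come from the GENCODE M21 annotation of GRCm38, the assembly also called mm10. Overlap between hairpins was judged by shared stretches of 18 bases.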

Results

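The data were read counts of mature miRNAs in 15 mouse libraries of small RNA. A miRNA hairpin yields a mature strand from its 5p arm, its 3p arm or both, and the title of the series concerns the switch of the dominant arm and its regulation by uridylation, the addition of uridines to RNA ends. The comparisons below ask where arm usage and abundance differed between tissues. Totals ranged from 148052 reads in testis to 3161463 in brain, and the next lowest was stomach with 922137. A count of 3 reads stood for 20.3 unscaled CPM in testis and 0.95 in brain, so that testis values were the least precise.

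The most abundant miRNAs were those known for each tissue in many libraries. The liver-specific miR-122-5p took 31.2% of liver reads, the cardiac and skeletal muscle miR-1a-3p 17.4% of heart reads, and the leukocyte miR-142a-3p 17.1% of spleen reads. The neural miR-9-5p led brain with 10.5%, spinal cord with 7.77%, the 11-day embryo with 6.32% and the 15-day embryo with 5.97%, and the neuronal miR-124-3p led eye with 9.21%. The erythroid miR-451a led the 17-day embryo with 7.62% and lung with 10.3%. Stomach was led by the smooth muscle miRNA miR-143-3p with 17.5%, salivary gland by miR-148a-3p with 11.6%, kidney by miR-30c-5p with 7.91%, and testis by the germ cell miRNA miR-34c-5p with 4.86%. The library labelled smooth muscle was led by miR-194-5p, known from gut epithelium, kidney and liver, with 14.8%.

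mir-324 used its 5p arm more in brain, spinal cord and embryos than in the other adult tissues. The 5p share was 63.1% in spinal cord (95% interval 60.5 to 65.8, 1297 reads), 59.97% in brain (58.1 to 61.8, 2783 reads), 63.1% in the 17-day embryo (61.3 to 64.9), 61.2% in the 15-day embryo (59.0 to 63.3) and 58.6% in the 11-day embryo (56.5 to 60.5). Eye, at 49.2% (45.9 to 52.5), lay among the other adult tissues. The lowest shares were found in stomach, at 26.3% (21.9 to 31.1, 369 reads), and liver, at 32.8% (27.0 to 39.0, 250 reads). Lung had 50.4%, heart 49.3%, kidney 46.5%, smooth muscle 45.3%, salivary gland 43.5%, spleen 43.1% and testis 40.5%, the last from 74 reads with an interval of 29.3 to 52.6.

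The mean share was 57.4% ± 7.3 in the nervous class (SD, n = 3) and 42.0% ± 7.8 in the other adult class (SD, n = 9), a difference of 15.5 points with an exact permutation p of 0.027. Of the 3 nervous libraries, 2 lay above all other adult libraries. The call was lost without brain (exact p = 0.073), without spinal cord (exact p = 0.091), and without testis and smooth muscle together (exact p = 0.05), the last an alternative chosen after seeing the data. The embryo mean was 60.9% ± 2.3 (SD, n = 3), a difference of 18.95 points with an exact permutation p of 0.0045, the smallest that the 220 splits allow. All 3 embryo libraries lay above all 9 other adult libraries. The embryo libraries are stages of 1 kind of sample, with a Pearson r of log2 CPM of 0.95 to 0.99 between them. The test takes them as independent units that could be exchanged with unlike adult organs, so its p may be too small.

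**Figure D1:**
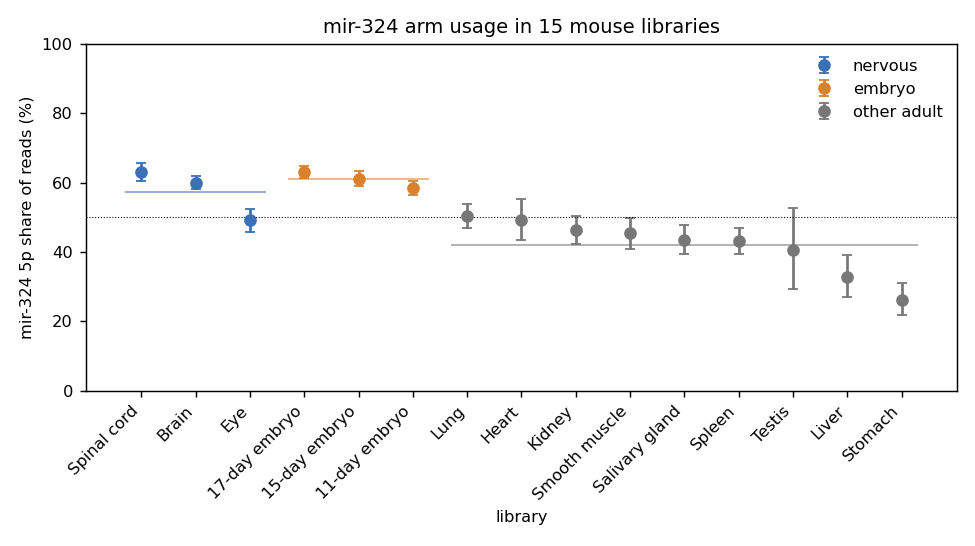
The share of mir-324 reads from the 5p arm, in percent, is plotted for each of the 15 libraries, with exact 95% binomial intervals as bars, horizontal lines at the class means and a dotted line at 50%. The embryo, brain and spinal cord libraries lie at 58.6% or above, and the 9 other adult libraries lie between 26.3% and 50.4%.

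The mir-324 hairpin (Mir324, 89 bases) lies on the plus strand of chromosome 11, from 70012043 to 70012131 in GRCm38. It overlaps an exon of Dvl2 on the same strand and an intron of Acadvl on the opposite strand, and its sequence is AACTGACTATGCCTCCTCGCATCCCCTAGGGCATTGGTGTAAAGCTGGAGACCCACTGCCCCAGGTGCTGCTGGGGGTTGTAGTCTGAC. The range of its share over the libraries was 36.9 points, rank 11 among 219 hairpins with at least 20 reads in at least 10 libraries, for which the median range was 5.89 points. On the log2 scale of the arm ratio its SD was 0.66, rank 134, where counting error alone gave 0.14. The median SD was 0.77, so on this scale mir-324 varied less than the median hairpin. The log2 scale gives more weight to hairpins with a rare minor arm. The scale in points gives more weight to hairpins that use both arms, such as mir-324.

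The dominant arm differed between libraries for 15 of 388 hairpins, or 3.87%. The 5p arm led in every decided library for 175 hairpins and the 3p arm for 177, and 21 could not be decided at this depth. Of the 15, 6 lie in the imprinted Dlk1-Dio3 region of chromosome 12, namely mir-154, mir-376b, mir-337, mir-299a, mir-136 and mir-329. A further 3, mir-1298, mir-1264 and mir-448, lie in introns of the serotonin receptor gene Htr2c on chromosome X. The others were mir-296, mir-34b, mir-324, mir-423, mir-297c and mir-669f. The last 2 lie in introns of Sfmbt2 on chromosome 2 and share 18-base stretches with many other hairpins there, so that their shares are uncertain. mir-376b shares such stretches with Mir376c and Mir487b, and mir-299a with Mir299b.

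For mir-154, mir-296, mir-376b and mir-448 the 5p share was lower in the 3 embryos than in each adult library with at least 20 reads of the hairpin. The 5p share of mir-154 was 88.9% in stomach (81.7 to 94.0, 117 reads) and 25.2% in the 11-day embryo (24.0 to 26.4, 5027 reads). mir-296 had 79.7% in brain (76.7 to 82.4) and 27.5% in the 11-day embryo (26.3 to 28.6), and mir-376b had 64.0% in spinal cord (61.8 to 66.0) and 6.89% in the 11-day embryo (6.23 to 7.59). mir-448 had 59.7% in spinal cord (53.2 to 66.1) and 8.33% in the 11-day embryo, there from 24 reads with an interval of 1.03 to 27.0. Only brain and spinal cord had at least 20 reads of mir-448 among the adult libraries. For the other 3 the interval of the lowest adult share took in the share of the 17-day embryo. For mir-376b liver had 13.95% (7.42 to 23.1) against 13.03% in that embryo, for mir-154 liver had 52.3% (36.7 to 67.5) against 40.3%, and for mir-296 smooth muscle had 44.4% (30.9 to 58.6) against 35.9%. Both mir-1298 and mir-34b differed between adult tissues. mir-1298 had 98.9% in lung (96.9 to 99.8) and 38.2% in spinal cord (33.4 to 43.3), and mir-34b had 88.4% in spleen (74.9 to 96.1, 43 reads) and 38.7% in eye (31.0 to 46.9). mir-423 had the narrowest range of the 15, from 39.5% in the 17-day embryo (37.9 to 41.1) to 59.1% in stomach (56.6 to 61.7). By contrast, the 5p shares of mir-320, mir-429 and mir-206 were at most 0.154%, 0.179% and 0.196% in any library with at least 20 reads.

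**Figure D2:**
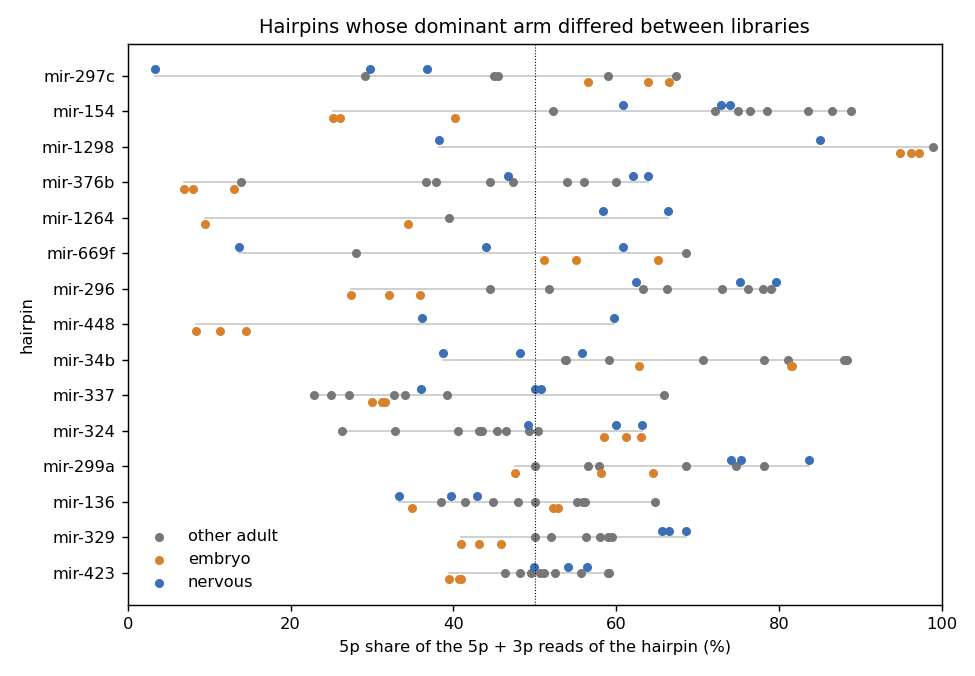
Each row is 1 of the 15 hairpins whose dominant arm differed between libraries, each point is the 5p share in percent in a library with at least 20 reads of the hairpin, colours mark the classes, and the grey line joins the lowest and the highest share. mir-154 extends from 25.2% to 88.9% and mir-423 from 39.5% to 59.1%.

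In the nervous class arm usage differed from the other adult class for 14 of 226 hairpins by edgeR, 3 with more 5p and 11 with more 3p. mir-431, a hairpin of the Dlk1-Dio3 region, fell from 94.1% ± 6.7 5p (SD, n = 8, 230 reads) to 55.5% ± 11.7 (SD, n = 3), a log2 odds change of -3.04 ± 0.46 (SE, adjusted p = 0.00014). The 4 other adult libraries with at least 20 of its reads had a mean of 89.5%. The neighbouring mir-434 fell from 29.9% ± 6.6 to 14.8% ± 1.4 (adjusted p = 0.0079), and mir-376c rose from 1.12% ± 1.69 to 12.7% ± 6.2 (adjusted p = 0.001), although its 5p side shares sequence with Mir376b. mir-20b had 72.9% ± 19.9 against 97.1% ± 2.4 (adjusted p = 0.0029, 87 nervous reads). Its nervous mean was lowered by brain, where 4 of 8 reads were 5p (95% interval 15.7 to 84.3). Eye and spinal cord had 83.3% and 85.5%, and without brain the log2 odds change was -2.30 (adjusted p = 0.041) in place of -2.77. The 5p share was also lower for mir-188, mir-671, mir-93, mir-33 and mir-328, and higher for mir-130b, at 34.4% ± 4.7 against 18.2% ± 7.3 (adjusted p = 0.013). mir-324 did not pass in this fit (log2 odds 0.91 ± 0.30, adjusted p = 0.059). The count was 4 without spinal cord, 6 without brain and 28 without stomach, and 3 hairpins passed whichever single library was left out. Without spinal cord the calls on mir-434, mir-188, mir-130b, mir-671, mir-93 and mir-33 were lost (adjusted p 0.063 to 0.19), and without brain those on mir-434, mir-130b, mir-328, mir-93 and mir-33 (0.05 to 0.11). Calls on mir-671 and mir-33 were lost without eye (both 0.068), and that on mir-33 without lung (0.054). limma on log2 ratios also called 14 hairpins, of which 8 were shared, and it lost mir-188 (adjusted p = 0.059) and mir-33 (0.21). In limma mir-324 did not pass either (adjusted p = 0.12). In edgeR it passed without stomach (adjusted p = 0.042), eye (0.046) or heart (0.049).

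In embryos arm usage differed from the other adult class for 46 of 226 hairpins by edgeR, 21 with more 5p and 25 with more 3p. The 5p share of mir-154 was 30.5% ± 8.5 (SD, n = 3) against 74.5% ± 12.5 (SD, n = 9), a log2 odds change of -2.997 ± 0.395 (SE, adjusted p = 4.7e-06). mir-376b fell to 9.32% ± 3.26 from 46.3% ± 15.7 (adjusted p = 1.6e-05), mir-296 to 31.8% ± 4.2 from 68.4% ± 13.2 (adjusted p = 0.00016), and mir-485 to 6.76% ± 0.38 from 23.8% ± 8.0 (adjusted p = 0.00018). mir-503 rose to 98.0% ± 0.5 from 86.3% ± 7.5 (adjusted p = 1.6e-05), and mir-23a to 0.873% ± 0.238 from 0.281% ± 0.128. The 3p side of mir-23a shares sequence with Mir23b, so its share is uncertain. mir-324 rose by 1.11 ± 0.29 in log2 odds (adjusted p = 0.0083). Its call was lost without the 15-day embryo (adjusted p = 0.051) or the 17-day embryo (0.053). Calls on mir-133b, mir-133a, mir-205 and mir-149, whose minor arms were rare, were lost in limma on log2 ratios, which called 19 hairpins. The 3p sides of mir-133a and mir-133b share sequence with each other. The count was 26, 21 and 29 without the 11-, 15- and 17-day embryo. Of the 46 hairpins, 17 were also called by limma, and 17 passed whichever single library was left out. In 22 of the 46 the mean share of the minor arm in embryos was above 5%.

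In abundance, the nervous tissues differed from the other adult tissues for 284 of 693 miRNAs by edgeR, 197 higher and 87 lower, and DESeq2 called 195 higher and 159 lower. The neuronal list rose in 15 of 17 members (15 adjusted over the list alone; fry adjusted p = 1.4e-05; adjusted p = 0.51 with an estimated correlation). miR-124-3p stood at 56886 ± 49623 CPM (SD, n = 3) against 160.1 ± 209.8 (SD, n = 9), a log2 fold change of 8.48 ± 1.07 (SE) that was 7.57 without eye and 9.15 without salivary gland. miR-9-5p rose by 6.90 ± 0.76 and miR-128-3p by 5.22 ± 0.67, the latter by 3.53 without brain and 5.81 without eye. All 4 members of the oligodendrocyte list rose (4 adjusted over the list alone; fry adjusted p = 0.00052; adjusted p = 0.79 with an estimated correlation), led by miR-338-3p (4.16 ± 0.56) and miR-219a-2-3p (8.36 ± 1.33). Without spinal cord these were 2.998 and 6.72, and miR-219a-2-3p was 8.95 without eye and 9.02 without smooth muscle. In the Dlk1-Dio3 list 40 of 41 members rose (40 adjusted over the list alone; fry adjusted p = 0.00021; adjusted p = 0.79 with an estimated correlation), among them miR-127-3p (4.23 ± 0.79, and 4.87 without stomach) and miR-434-3p (5.12 ± 0.71). Further large rises were those of miR-873a-5p (7.49 ± 0.68), miR-325-5p (7.30 ± 0.69), miR-124-5p (7.84 ± 1.09) and miR-770-3p (7.29 ± 0.79). miR-325-5p was 6.69 without spinal cord, and miR-124-5p was 6.81 without eye and 8.57 without testis. miR-3059-5p, miR-873a-3p and miR-1188-5p had no read in any other adult library and were at least 169-fold, 140-fold and 38.3-fold higher.

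All 4 members of the smooth muscle list, made from the miR-143 and miR-145 hairpins, fell in the nervous class (4 adjusted over the list alone; fry adjusted p = 0.021; adjusted p = 0.84 with an estimated correlation), with miR-143-3p at -3.31 ± 0.93 (-4.16 without eye). In the miR-17-92 list, a family linked to proliferation, 11 of 13 members fell (12 adjusted over the list alone; fry adjusted p = 0.013; adjusted p = 0.82 with an estimated correlation), such as miR-93-5p (-1.92 ± 0.50) and miR-25-3p (-1.87 ± 0.51). Both list calls were lost without brain (fry adjusted p = 0.058), and that on smooth muscle also without spinal cord (0.058). Without brain 2 smooth muscle and 3 miR-17-92 members fell, and without spinal cord 5 miR-17-92 members did. The leukocyte miRNAs miR-142a-3p (-6.35 ± 1.77) and miR-223-3p (-3.61 ± 0.97) and the hepatic miR-122-5p (-10.89 ± 4.03, adjusted p = 0.042) were lower. The size for miR-122-5p was set by liver, at 619675 CPM against 120 to 2166 in the other 8 tissues of the class, and without liver it was -4.62 (adjusted p = 0.015). Without eye it was -12.01. Without spleen, miR-142a-3p changed by -4.86. The call on miR-122-5p was lost without brain (adjusted p = 0.14), spinal cord (0.14), eye (0.09) or the 15- or 17-day embryo (0.057 and 0.056), and those on miR-142a-3p (0.053) and miR-143-3p (0.052) without brain. That on miR-122-5p was also lost with no filter on low counts (adjusted p = 0.065) and with only the 12 libraries of the 2 classes (0.059). In the list of retina, pigment epithelium and lens 6 of 6 members rose (6 adjusted over the list alone), with a median log2 fold change of 5.49, but the list did not pass (fry adjusted p = 0.075). Without eye 1 member rose, miR-204-5p (3.59, adjusted p = 0.012), which is named after its values were seen, and the list had a fry adjusted p of 0.44, whereas it passed without brain (0.046) or spinal cord (0.022). In the leukocyte list 4 of 5 members fell (4 adjusted over the list alone), and 1 did without brain. It did not pass (fry adjusted p = 0.075), except without spleen (0.027) or testis (0.044). Of the other lists, none of which passed (0.15 to 0.89), 2 of 2 hepatocyte, 2 of 3 kidney and gut epithelium and 2 of 4 erythroid members fell (2, 3 and 3 adjusted over the list alone), and 0 did without brain, spinal cord or eye. The count was 186 without brain. Scaling to total counts moved the median log2 fold change of all miRNAs by 0.47, and with it 226 were higher and 56 lower, so that changes hold relative to this shift. The miR-17-92 list did not pass with that scaling (fry adjusted p = 0.061), under which 8 of its members fell.

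Embryos differed from the other adult tissues for 306 of 693 miRNAs by edgeR, 187 higher and 119 lower, and DESeq2 called 194 higher and 182 lower. All 4 members of the H19 and Igf2 list, miRNAs hosted by imprinted genes of fetal growth, rose (4 adjusted over the list alone; fry adjusted p = 7.8e-08; adjusted p = 0.51 with an estimated correlation). miR-483-3p stood at 830.3 ± 136.4 CPM (SD, n = 3) against 2.73 ± 2.96 (SD, n = 9), a log2 fold change of 8.46 ± 0.74 (SE), and miR-675-3p rose by 6.56 ± 0.91. All 41 members of the Dlk1-Dio3 list rose (41 adjusted over the list alone; fry adjusted p = 3.5e-06; adjusted p = 0.51 with an estimated correlation), with miR-376a-3p at 5.97 ± 0.69, miR-380-3p, outside the list, at 7.22 ± 0.76 and miR-370-3p at 6.82 ± 0.86 (7.46 without stomach). Of the neuronal list 6 of 17 members rose (6 adjusted over the list alone; fry adjusted p = 0.011; adjusted p = 0.89 with an estimated correlation), such as miR-9-5p (5.58 ± 0.73) and miR-124-3p (4.74 ± 0.96, and 5.41 without salivary gland), while miR-218-5p changed by 0.84 ± 1.03 (adjusted p = 0.53), and by 2.10 without salivary gland (adjusted p = 0.027). miR-135a-1-3p and miR-1188-5p had no read in any other adult library and were at least 54.8-fold and 52.0-fold higher. The early embryonic clusters rose in 5 of 5 tested members (5 adjusted over the list alone; fry adjusted p = 0.045; adjusted p = 0.89 with an estimated correlation), carried by the 11-day embryo, where miR-295-3p had 389.9 CPM. Without that embryo 1 member rose and the list did not pass (fry adjusted p = 0.25), nor did it without brain, heart, kidney, liver, lung, salivary gland, smooth muscle, spleen or stomach (0.05 to 0.078). Without testis 2 members could be tested, and both rose.

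Among the largest falls in embryos was that of miR-29a-3p, a miRNA that targets collagen and other matrix genes. It stood at 428.3 ± 215.3 CPM against 35675 ± 14930 (log2 fold change -6.38 ± 0.73, adjusted p = 1e-05, and -6.98 without the 11-day embryo), miR-29b-3p changed by -6.22 ± 0.85 and miR-29c-3p by -5.70 ± 0.86. Of the let-7 family, which accumulates during differentiation, 6 of 9 members fell (6 adjusted over the list alone; fry adjusted p = 0.00071; adjusted p = 0.79 with an estimated correlation), among them let-7b-5p (-4.15 ± 0.70) and let-7c-5p (-2.92 ± 0.56, and -3.54 without the 15-day embryo). All 4 smooth muscle members fell (4 adjusted over the list alone; fry adjusted p = 0.021; adjusted p = 0.84 with an estimated correlation), a call lost without the 11-day embryo (0.054). The lymphocyte miRNA miR-150-5p changed by -7.32 ± 1.57, and by -6.43 without spleen, and the immune miR-146a-5p by -4.91 ± 0.97. miR-547-3p and miR-201-5p, at 183.1 ± 499.3 and 327.1 ± 901.0 CPM in the other adult class, were lower (log2 fold change -9.36 and -8.86). Testis held most of both, with 1512 and 2727 CPM, where heart was next with 94.3 and 146 CPM, and without testis the changes were -5.94 and -5.25 (adjusted p = 0.0047 and 0.012). Neither call held without the 11-day (adjusted p = 0.075 and 0.098), 15-day (0.076 and 0.1) or 17-day embryo (0.065 and 0.082), although without the 17-day embryo the changes were larger, at -10.20 and -9.82. In the leukocyte list 4 of 5 members fell (5 adjusted over the list alone), and 1 or 2 did without any 1 embryo, lung, smooth muscle or spleen. It did not pass (fry adjusted p = 0.085), except without spleen (0.034) or testis (0.0499). Both endothelial members fell (2 adjusted over the list alone), 0 without any 1 embryo, and that list did not pass (0.12), nor did the others (0.46 to 0.96). The striated muscle list had a median log2 fold change of -3.13 where its fry direction was up (0.55). Scaling to total counts moved the median log2 fold change by 1.28, with 287 higher and 42 lower. The let-7 and smooth muscle lists did not pass with that scaling (both fry adjusted p = 0.061), under which 5 let-7 members fell and 1, let-7e-5p, rose (1.27, adjusted p = 0.047, against -0.15 and 0.83 with TMM). It was named after its values were seen.

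By size alone, without a test, 164 miRNAs were enriched in a single library, of which 71 in testis, 19 in heart, 15 in eye and 12 in brain. Testis was led by miR-34c-5p at 31570 CPM (exact Poisson 95% interval 30845 to 32308) and the gonadal miR-202-5p at 19814 CPM. Liver had miR-122-5p at 108 times the next library, and heart had miR-1a-3p at 19.3 and miR-133a-3p at 12.03 times. These folds depend on the scaling and would be smaller by unscaled share of reads. The TMM factors were 0.503 for liver and 0.449 for heart, against 1.92 for the 15-day embryo and 0.825 for eye, their next libraries. Eye was led by miR-124-3p, the photoreceptor miRNA miR-182-5p (18.9 times) and miR-184-3p, known from lens and cornea (428 times). Spinal cord was led by miR-338-3p and miR-219a-2-3p (3.09 and 4.07 times, with brain next), brain by miR-128-3p (4.22 times) and miR-132-3p (2.90 times), and spleen by miR-142a-3p (7.07 times). Smooth muscle was led by miR-194-5p at 6.04 and miR-215-5p at 100 times the next library. The 11-day embryo had 10 enriched miRNAs, among them miR-130b-3p (2.02 times) and the early embryonic miR-295-3p and miR-294-3p, at 12.7 and 13.4 times the next library, testis. Among the smaller sets, kidney had miR-10a-5p (2.15 times), salivary gland miR-148a-3p (3.26 times), stomach miR-672-5p (2.21 times), lung miR-146b-5p (2.27 times) and the 17-day embryo miR-673-5p (2.52 times). The 15-day embryo had 0.

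Of 285 pairs of a list and a library, 59 lay in the top 2.5% of matched random lists, where chance gives 7.12 for lists of unrelated miRNAs. Several lists hold both arms of a hairpin or members of 1 cluster, which can move together, so 7.12 may understate chance for them. The neuronal list did so in brain, spinal cord, eye and the 15-day embryo, and the oligodendrocyte list in brain, spinal cord and eye. The hepatocyte list did so in liver and the 17-day embryo, the testis list in testis, the list of retina, pigment epithelium and lens in eye and salivary gland, and the striated muscle list in heart, eye, lung and the 15- and 17-day embryos. The smooth muscle list was high in smooth muscle, stomach and heart. The kidney and gut epithelium list was high in kidney, liver, stomach and smooth muscle, and the epithelial list in lung, salivary gland, stomach and smooth muscle. The leukocyte list was high in spleen, lung, salivary gland, stomach and smooth muscle, the erythroid list in lung and spleen, the endothelial list in lung, and the endocrine list in stomach and smooth muscle. Hox-cluster miRNAs were high in kidney, spinal cord, testis, smooth muscle and the 11- and 15-day embryos, and the miR-17-92 list in spleen, testis, smooth muscle and the 11-day embryo. The Dlk1-Dio3 list was high in the nervous and embryo libraries, the H19 and Igf2 list in the 3 embryos, and the early embryonic list in the 11- and 15-day embryos. The let-7 list was in the top 2.5% in no library. With a pseudocount of 10 CPM in place of 1, 50 of the 59 pairs stayed in the top 2.5% and 0 joined them. The percentile dropped out of that range for the 9 others, namely the neuronal list in the 15-day embryo (97.73 to 83.79), the early embryonic list there (99.42 to 92.77), the Dlk1-Dio3 list in eye (98.88 to 94.43) and Hox-cluster miRNAs in smooth muscle (97.86 to 93.95) and testis (99.12 to 96.95). The same held for the endocrine list in smooth muscle (98.67 to 95.57), the hepatocyte list in the 17-day embryo (97.53 to 96.65) and the striated muscle list in the 15-day (97.72 to 96.92) and 17-day embryo (98.17 to 96.27).

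**Figure D3:**
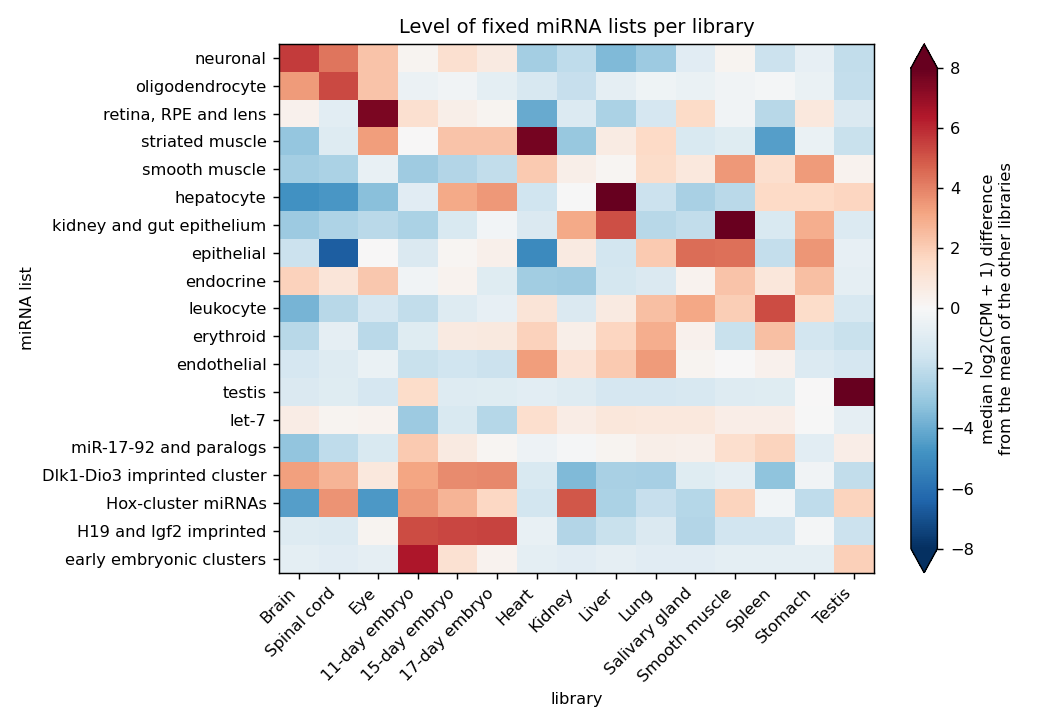
Each cell gives, for a miRNA list (row) in a library (column), the median over its members of log2(CPM + 1) minus the mean of the other 14 libraries, with red for higher and blue for lower levels and colours saturated at the ends of the scale. The H19 and Igf2 list is high in all 3 embryos, and the kidney and gut epithelium list is high in the smooth muscle library.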

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

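The tests of a general 5p shift, of shared sequence, of the gut and cardiac miRNAs and of the splits of the libraries were chosen or written down after the result was seen, and the test against neuronal miRNAs was written before its result.

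The gap of a library to its nearest neighbour was examined in 67 sets of values over the other adult tissues. In 11 of them a library had a gap that was large for the range of the set. A chance count of about 3.35 would hold only for sets not chosen by their values. Many hairpins and miRNAs here were named for a wide range, a low p-value or a large class difference. Some sets also held shares near their upper limit or levels of 0. The 11 can therefore not be compared with 3.35, and how many arise by chance is not known. miRNAs named only for being high in a single tissue were not among these sets. The testis total of 148052 reads stood apart (gap 0.61 of the range on the log2 scale). For 5p shares, stomach stood apart for mir-337 (65.9% against 22.9 to 39.2, gap 0.62) and mir-188 (78.7% against 92.3 to 96, gap 0.786), liver for mir-154 (52.3% against 72.2 to 88.9, gap 0.544) and testis for mir-130b (35.9% against 13.1 to 21.5, gap 0.633). Heart stood apart for mir-33 (71.8% against 87.5 to 96.9, gap 0.626), kidney for mir-205 (99.7%, gap 0.574) and salivary gland for mir-149 (97.3%, gap 0.752). Liver stood apart for miR-122-5p (gap 0.662) and miR-122-3p (gap 0.651), and salivary gland for miR-1251-5p, at 1.27 CPM against 0 in the other 8 (gap 1).

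The first pattern is the higher 5p share of mir-324 in embryos, brain and spinal cord. A general shift of hairpins toward the 5p arm in embryos is argued against by the median log2 odds difference over 226 hairpins, 0.0264 with an SD of 1.01, against 1.11 for mir-324. In the nervous class the median was -0.0168 with an SD of 0.94, against 0.91 for mir-324. Of the 14 hairpins called there, 3 went toward 5p and 11 toward 3p, so these values argue against a general 5p shift there too. The gap between mir-324 and the median lay within the SD between hairpins, so mir-324 did not stand apart from the other hairpins in that class. Reads shared with another hairpin are argued against by 0 other annotated hairpins with an 18-base stretch in common. Over the 9 other adult tissues, the level of the neuronal list and the share had a Spearman rho of -0.183 (exact permutation p = 0.64) and a Pearson r of -0.15 (exact permutation p = 0.68; -0.54 without liver and testis, exact permutation p = 0.17; 1 relation tested), a value below 0 by less than its spread, which leaves open whether neuronal RNA sets the share, and a difference in processing between tissues was not tested.

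The second pattern is the gut-type profile of the smooth muscle library, with miR-194-5p at 259058, miR-215-5p at 169074 and miR-192-5p at 61866 CPM. Carry-over from another library of this series is argued against by miR-194-5p at 6.04 times the highest other library. Intestinal epithelium in the sample is a possible explanation, as the epithelial list, which holds none of these miRNAs, stood at percentile 99.97, with miR-200b-3p at 28232 CPM. The same list is high in stomach and salivary gland, so it does not single out intestine. The smooth muscle list stood at percentile 99.8, and which organ the sample came from is not given in the sources used here.

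The third pattern, chosen after its values were seen, is a set of cardiac miRNAs in lung. miR-208a-3p had 519 CPM (exact Poisson 95% interval 489 to 551), 4.55% of its heart level, and miR-208b-3p had 144 CPM. Heart RNA or heart reads as the source of the miR-208a-3p level would need 1018 CPM of miR-499-5p, but the library had 20.2 (14.5 to 27.3), or 1.98% of that. By the same measure miR-208a-5p reached 13.5%, miR-133a-3p 24.5%, miR-1a-3p 38.6%, miR-133b-3p 42.6% and miR-378a-3p 59.8% of the level needed, while miR-208b-3p (468%) and miR-486a-5p (574%) exceeded it. A smaller share of heart RNA is not excluded, and no biological explanation was tested.

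Other splits of the 12 libraries into 3 and 9 were fitted for 100 of the 220 possible splits, the real one included. For abundance, 1 of 100 splits gave as many calls in the nervous comparison, the real one with 284, and the highest other gave 173. In the embryo comparison 1 of 100 did, the real one with 306, and the highest other gave 40. For arm usage in embryos 1 of 100 did, the real one with 46, and the highest other gave 19. For nervous arm usage 2 of 100 did, the real one with 14 and the split of lung, salivary gland and spleen with 20. In each comparison at most 2 of 100 fitted splits gave as many calls, which is past the 0.05 level, so a random division of these libraries rarely did. The test was chosen after the results and not adjusted over the comparisons, so it does not exclude chance. It was least clear for nervous arm usage, where another split gave more calls than the real one. For nervous abundance the split with 173 calls held brain, heart and spinal cord. Brain and spinal cord gave 113 calls with salivary gland and 104 with lung, and every remaining fitted split gave at most 17. Much of the real count of 284 therefore goes with brain and spinal cord together, and not with a class that includes eye.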

How the results depend on the processing

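The removal of the testis and smooth muscle libraries together, and mean shares over libraries with at least 20 reads, were chosen after seeing the data. The 15 arm switches became 11 to 18 under other intervals, read minimums and sizes and 13 to 15 with a library left out, and the mir-324 range stayed between 30.3 and 36.9 points. The nervous difference in mir-324 share was 12.6 to 19.6 points with a library left out, and 15.7 (exact p = 0.05) without testis and smooth muscle. The count of arm usage was 4 to 28 (nervous) and 21 to 50 (embryo) with a library left out, and 19 by limma in embryos. The nervous abundance count was 186 to 303 with a library left out. Of the 11 list calls, 0 held in camera with an estimated correlation, which asks a different question. Tissue-enriched miRNAs fell to 90 at a minimum of 1000 CPM, which removes rarer miRNAs by construction. mir-205 reversed in embryos under limma (log2 odds 0.10, adjusted p = 0.95), and miR-294-3p reversed without the 11-day embryo (-0.31, adjusted p = 0.92) and reached up to 6.55 with another library left out. let-7e-5p, not called in embryos, was 1.27 with total counts (adjusted p = 0.047) and -0.57 to 0.0203 with a library left out, its only value above 0 being that without the 17-day embryo. Apart from the CPM minimum, the cause was not tested. Of 1277 alternative fits of the 60 named class differences, 1231 kept direction and side of the threshold, 45 lost the call and 1 reversed. The 45 losses fell on 18 of the 60 differences, each of which lost its call in at least 1 alternative. Scaling to spike-ins was not run, since no spike-in is listed. Depth limits testis most.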

Other observations

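The test of cluster membership was chosen after the result was seen, as were the miRNAs named here. Several libraries carried miRNAs better known from other tissues. Eye held the striated muscle miRNAs miR-1a-3p at 20125 CPM and miR-206-3p at 1846 CPM. Salivary gland held the leukocyte miRNA miR-142a-3p at 29994 CPM, close to lung at 31234, and the endocrine miRNA miR-375-3p at 12325 CPM. Smooth muscle had 10956 CPM and stomach 5731 CPM of miR-375-3p. Spleen held miR-216a-5p at 323.7 CPM and miR-217-5p at 154 CPM, which are known from pancreas. Stomach had 114 and 157 CPM, eye 55.0 and 118 CPM, and smooth muscle 72.1 and 86.3 CPM of the same miRNAs. Lung held miR-34c-5p at 4665 CPM and miR-449a-5p at 803 CPM, miRNAs known from testis and from ciliated epithelium.

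A hypothesis is that hairpins of the Dlk1-Dio3 cluster may be over-represented among arm switches. Of the 343 hairpins with at least 20 reads in at least 2 libraries, 37 belonged to the cluster, and 6 of the 15 switches did (odds ratio 6.39, Fisher's exact p = 0.0026). The cluster was noticed in these same data, and its hairpins are expressed together, so the test treats as independent what may not be. The low counts of these hairpins in adult tissues were not weighed.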
